A study of Homo sapiens with 24 samples.

How the data were processed

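The series holds 24 RNA libraries of HaCaT keratinocytes, 3 for each of 8 groups made by construct (empty vector or hsa-miR-186), dose (0 or 100 nM iAs) and week (12 or 29). Per the labels' protocols, total RNA was isolated with the mirVana kit, libraries were made from 1 µg with the TruSeq Stranded mRNA kit, and all samples were pooled and sequenced together, paired-end, on an Illumina NextSeq instrument. Reads were aligned with STAR 2.6.0c to hg38 (GRCh38), and FPKM were made with Cuffdiff 2.2.1 by the authors, per the submitters' processing notes. The annotation release, the strand setting of the counting and any scaling between libraries beyond FPKM are not given there. The deposited FPKM were used as they stand, and read counts were not used here. Antisense genes are not named, because without a known strand setting their reads cannot be assigned to a strand.

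The deposited table has 58381 gene IDs, of which 57740 have a symbol and 58261 are in GENCODE release 29, which gave coordinates, gene GC content and 3' UTRs. Sums of FPKM ran from 712800 to 905680 per library, and 13803 to 14588 genes reached 0.5 FPKM. The 10 highest genes held 13.3% to 24.8% of the FPKM. Without read counts, absolute depth was not measured. Relative depth was estimated from the smallest common step of FPKM times transcript length, at the 5th percentile over 17613 genes with a single transcript over 500 bases, and ran from 0.825 to 1.08. No pair of libraries had identical values, and each library's highest correlation with another, across genes that are not independent replicates, was 0.966 to 0.988.

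Values were analysed as log2(FPKM + 0.5) for the 14228 genes with a mean of at least 0.5 FPKM over the 24 libraries. limma 3.58.1 (R 4.3.3) was fitted to all 8 groups together, with an intensity trend and robust moderation, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Of 15 comparisons, 10 set 1 group against another and 5 were differences between such effects. Groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Of 35 gene lists, 31 had at least 4 measured members and were tested with limma's camera at its preset correlation of 0.01, and again with a correlation estimated from the data, giving 465 tests adjusted together. Members were also adjusted over their list alone. Genes per chromosome were tested with 1-sided Fisher's exact tests against all genes tested, a test chosen after the data were seen.

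Named genes were chosen by a rule. ZRANB2 and MIR186 come first. In each comparison the rule takes, among genes past the threshold with a mean of at least 1 FPKM in the higher group and no overlap between the libraries of the 2 groups, the 10 largest rises and the 10 largest falls. Where fewer than 3 pass in a direction, it takes the 5 with the smallest p, given as values. It adds up to 4 members with the smallest p of each list described. Genes without a symbol, joined genes, clone names, small RNA and ribosomal RNA genes, pseudogenes and genes of the sex chromosomes that mark a donor were left out. Not every gene the rule takes is printed, and some of their results are not reported here. Genes passing in all 4 comparisons between constructs are named from those results, and MED1, CDK12, CASC3, SMARCE1, ORMDL3 and RIPK3 among them were chosen after their values were seen.

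For the seed test, each gene's longest annotated 3' UTR was searched for the 8mer ATTCTTTA among 19110 protein-coding genes with one. Genes with the site were set against genes without the 6mer TTCTTT, and the difference of medians was ranked among the 168 8mers with the same bases. The correction for GC content fits a natural spline of 5 degrees of freedom over gene GC content to each library, set by genes above 1.5 FPKM, and covers 14208 genes (99.9%). Genome windows are 20 Mb wide with at least 40 genes, and each gives the median of GC-corrected deviations from the mean over the 24 libraries. The corrections for GC content and windows were chosen after the data were seen.

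The replicate number was checked as a possible pairing before any blocked counts were compared. The correlations of deviations from the group means were 0.49, 0.46 and 0.62 for numbers 1, 2 and 3 in the iAs comparison of vector clones at week 29. They were 0.31, 0.52 and 0.17 between weeks in vector clones at 0 nM, and 0.21, 0.23 and 0.20 between constructs at 0 nM and week 29, where the labels give different clones to each construct. These are across genes, which are not independent replicates. Only in these 3 of the 10 comparisons of 2 groups did every number exceed 0.1, and there the number was treated as pairing the libraries, from the data and not from the labels. Between constructs the number cannot mark a shared clone, and what the correlations there reflect was not tested. The check used values without the GC correction. Alternatives were a pseudocount of 0.1 or 1, no filter, a mean of at least 2 FPKM, median ratio scaling, only the groups compared, the replicate number as a fixed block, construct and replicate number, which the labels do not tie to a clone, as a random block, the 2 corrections, the GC correction with the block, and leaving out each library.

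The steps were tested on simulated data. In the iAs comparison of vector clones at week 12, with 100 genes moved by log2 1 and 100 by log2 2 among 14085 genes, 58 and 91 were recovered, and 5 unchanged genes were among 154 called. With a GC trend added, 193 unchanged genes of 14120 were called without the correction and 5 with it, and 154 of 200 changed genes were recovered with it. The added trend was linear, the same in each treated library, and smaller than the difference between the real groups' slopes. The correction was therefore not checked on a trend that varies between libraries. A moved list was called, with no other list (14101 genes), and a whole moved window of −0.50 went to 0.02 after centring (14091 genes). Simulated genes were independent of each other, so the list test was not checked with correlated members. In the comparison of constructs at 0 nM and week 12, moved seed sites ranked 1 (difference −0.11, 14228 genes). Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for annotation and figures.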

Results

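HaCaT is an immortalised, non-malignant line of human keratinocytes. Per the labels, 3 clonal lines carried an empty vector and 3 carried hsa-miR-186. Each was kept in 0 or 100 nM inorganic arsenic (iAs), with RNA taken at weeks 12 and 29, which makes 8 groups of 3 libraries. Nothing but the labels, which call the samples independent biological triplicates, says what a replicate is, and the labels do not tie a replicate number to a clone. Changes are given as log2 changes ± standard error on log2(FPKM + 0.5), a scale that understates changes of genes with low levels. Levels are mean FPKM ± SD over n = 3 libraries per group.

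The microRNA gene MIR186 (ENSG00000207721, GRCh38 chromosome 1, 71067631 to 71067716, minus strand) lies inside ZRANB2 (ENSG00000132485, 71063291 to 71081297, minus strand), which encodes a zinc finger protein of pre-mRNA splicing. MIR186 was listed at 0 in all 24 libraries, and libraries made from poly(A) RNA do not measure a mature microRNA. ZRANB2 stood at 31.7 ± 7.55 FPKM in vector clones and 32.0 ± 0.937 FPKM in miR-186 clones at 0 nM and week 12, and at 24.8 ± 4.99 and 45.3 ± 17.5 FPKM at week 29. At 100 nM it stood at 28.6 ± 1.64 and 34.7 ± 2.02 FPKM at week 12, and at 28.9 ± 6.77 and 35.4 ± 4.29 FPKM at week 29.

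At week 12, the nuclear RNA NEAT1, the scaffold of paraspeckles, was higher with iAs in vector clones by 1.40 ± 0.25 (2.65-fold; 170 ± 51.7 FPKM with iAs and 62.4 ± 9.56 FPKM without, n = 3). LAMA5, a laminin chain of basement membranes, rose by 1.52 ± 0.32 (37.0 ± 2.14 against 13.1 ± 4.30 FPKM), and SERPINF1, a secreted serpin that restrains vessel growth, by 1.46 ± 0.29. Other rises among those with the greatest change were LCN12 (1.81 ± 0.39), LENG8 (1.69 ± 0.33), MAPK8IP3 (1.59 ± 0.35) and ANO9 (1.42 ± 0.34). LASTR (−1.21 ± 0.23), BPGM (−1.20 ± 0.30), STK38L (−0.98 ± 0.19), MMADHC (−0.96 ± 0.21), HBP1 (−0.89 ± 0.20) and PLS3 (−0.89 ± 0.20) fell, as did MRPL42 (−0.90 ± 0.20) and MRPL50 (−0.89 ± 0.21) of the mitochondrial ribosome. Of the genes named for this comparison, NEAT1 alone passed with a correction for GC content as well.

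Few members of the gene lists passed the test in that comparison. Of 15 basal keratinocyte genes 0 rose and 1 fell, the integrin ITGB1 (−0.69 ± 0.14; 0 and 2 adjusted over the list alone). Of 24 junction genes the tight junction gene TJP3 rose (1.51 ± 0.31), and of 27 NRF2 antioxidant genes the exporter ABCC3 rose (1.01 ± 0.19), with no fall in either list (1 and 0 adjusted over the list alone in each). Of 9 AHR target genes 1 fell, NFE2L2 (−0.61 ± 0.14), which encodes NRF2 itself (1 and 1 adjusted over the list alone), and of 51 mitosis genes 1 rose, ANAPC2 (0.90 ± 0.21; 1 and 0 adjusted over the list alone). None of the 5 metallothioneins, which bind metals, passed (1 and 0 adjusted over the list alone), with MT2A at 1.67 ± 0.56. The medians of 46 ribosomal protein genes (−0.29, adjusted p = 0.00773) and 20 heat shock genes (−0.23, adjusted p = 0.0321) lay below 0, with no member past the test (0 and 8, and 0 and 3, adjusted over the list alone). These were adjusted p = 0.922 and adjusted p = 0.890 with an estimated correlation.

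In the whole comparison limma gave 93 rises and 104 falls among 14228 genes at adjusted p under 0.05. The smallest adjusted p in limma was 0.0356, so all these calls lay near the threshold, and 4168 genes had unadjusted p under 0.05. With median ratio scaling limma gave 168 and 326. It gave 0 without a filter on low values and 0 in a fit on only these groups (5294 and 4132 at unadjusted p under 0.05). More genes passed than in the main fit with the replicate number as a fixed or random block, and fewer with the GC correction and the fixed block. Those counts stand with the processing alternatives below, because not every number passed the pairing check. Log2 deviations of genes from their mean over the 24 libraries changed with gene GC content. The slope was −0.149 ± 0.0652 per 10 points of GC in the untreated group and 0.287 ± 0.123 in the treated group, relative to that mean. The rises had a median GC content of 59.6% against 40.03% for the falls. A correction for GC content left 7 genes, among them 5 of the 197, NEAT1 included (1.63 with the correction). The median change of the 197 went from 0.84 to 0.47 with a median SE of 0.183 and 0.149, and leaving out any 1 of the 6 libraries left 0 (without vector 0 nM replicates 1 or 3, or vector 100 nM replicate 2; limma at unadjusted p under 0.05 gave 3380, 3771 and 3726) or 1 gene (without the others).

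**Figure D1:**
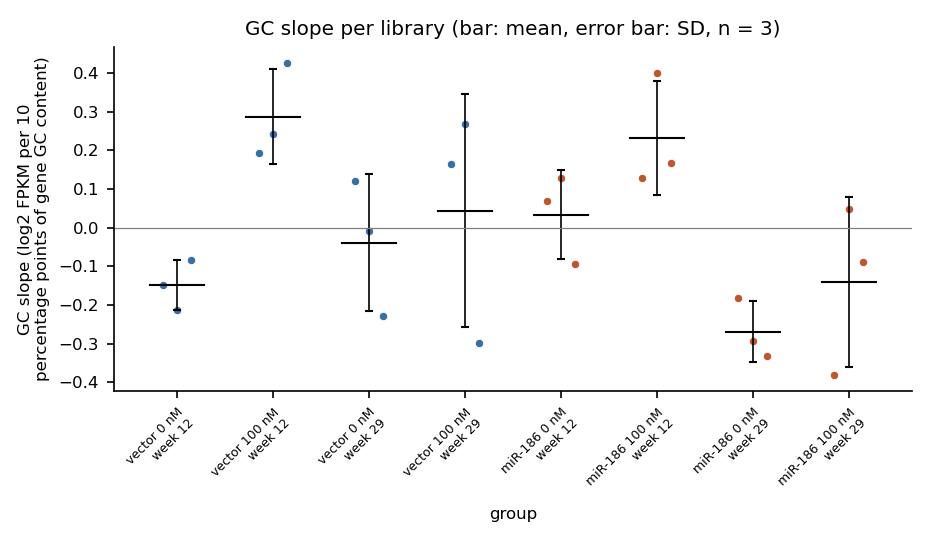
Slope over gene GC content in each of the 24 libraries (points), by group. It was fitted to each gene's log2 deviation from its mean over the 24 libraries, so signs are relative to that mean. Bars give the group mean and error bars the SD (n = 3). Slopes ran from −0.38 to 0.43 log2 per 10 points of GC.

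At week 29, no gene passed the test for iAs in vector clones. RGS3, a regulator of G protein signalling, stood at 14.8 ± 0.537 FPKM with iAs and 7.56 ± 1.15 FPKM without (0.93 ± 0.20, n = 3), and SOX9, a transcription factor of hair follicle stem cells, at 10.6 ± 0.627 and 6.47 ± 0.914 FPKM (0.67 ± 0.17). The splicing regulator TRA2A (0.62 ± 0.14), FBXL5, which controls iron regulatory proteins (−0.77 ± 0.20), RNLS (−1.19 ± 0.32) and the p53-induced SESN1 (−0.77 ± 0.21) had small unadjusted p as well. limma gave 0 genes, 555 at unadjusted p under 0.05, and adjusted p = 1 for each gene named here. Among the lists, the median of 35 type I interferon genes was −0.47 (adjusted p = 2.08e-11; adjusted p = 0.864 with an estimated correlation), with OAS2 at −1.09 ± 0.37. The median of 51 mitosis genes was 0.41 (adjusted p = 8.11e-05; adjusted p = 0.890 with an estimated correlation), and no member of either list passed (0 and 0 adjusted over the list alone).

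In miR-186 clones at week 12, no gene passed the test for iAs. L3HYPDH, a hydroxyproline dehydratase, stood at 46.5 ± 3.45 FPKM with iAs and 25.1 ± 2.92 FPKM without (0.88 ± 0.17, adjusted p = 0.247, n = 3). CD59, which blocks the complement pore, stood at 153 ± 32.6 and 235 ± 8.51 FPKM (−0.64 ± 0.14), CCNL2, a cyclin of splicing, at 100 ± 11.9 and 60.8 ± 9.39 FPKM (0.72 ± 0.16), and TRAF3IP3 at −1.27 ± 0.27. The 13 messages of the mitochondrial genome had a median of 0.69 (adjusted p = 2.50e-07; adjusted p = 0.890 with an estimated correlation), with MT-ND2 at 0.80 ± 0.21 and MT-CO2 at 0.73 ± 0.20. None of them passed over all genes (11 and 0 adjusted over the list alone). Of 51 mitosis genes none passed either (0 and 0 adjusted over the list alone), with a median of −0.45 (adjusted p = 1.70e-06; adjusted p = 0.890 with an estimated correlation). limma gave 0 genes, 1558 at unadjusted p under 0.05. With the correction for GC content 1 gene passed, 19 without a filter on low values, and 1 each without miR-186 0 nM replicate 1 or replicate 3.

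At week 29, no gene passed for iAs in miR-186 clones. ADAMTS6, a secreted metalloprotease, stood at 5.15 ± 0.731 FPKM with iAs and 2.16 ± 0.527 FPKM without (1.10 ± 0.26, n = 3), LY6K at 0.85 ± 0.22, DCP1A, a factor of mRNA decapping, at −0.76 ± 0.19 and ELK4 at −0.61 ± 0.18. The median of 27 NRF2 antioxidant genes was 0.27 (adjusted p = 2.61e-06; adjusted p = 0.814 with an estimated correlation), with HMOX1, which degrades heme, at 1.49 ± 0.60 and the aldo-keto reductase AKR1C1 at 1.25 ± 0.48. The median of 35 interferon genes was −0.45 (adjusted p = 2.18e-06; adjusted p = 0.890 with an estimated correlation). No member of either list passed (0 and 0 adjusted over the list alone). limma gave 0 genes, 312 at unadjusted p under 0.05, and 3 without a filter on low values.

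No gene passed the test for a difference in its iAs effect between constructs or between weeks. SOX9 had the smallest p between weeks in vector clones: its iAs effect was 1.32 ± 0.24 higher at week 29 than at week 12, followed by KDM6A, a histone demethylase, at 1.26 ± 0.24 (adjusted p = 0.215 for both, n = 3 libraries per group). In the same comparison NEIL1, a DNA glycosylase, stood at −1.81 ± 0.38 and NEAT1 at −1.39 ± 0.35. Between constructs, the epithelial transcription factor ELF3 stood at −0.96 ± 0.26 at week 12 and DCP1A at −1.07 ± 0.27 at week 29. ADAMTS6 stood at 1.78 ± 0.37 between weeks in miR-186 clones. limma gave 0 genes in each of the 4 comparisons, with 421 and 272 at unadjusted p under 0.05 between constructs at weeks 12 and 29, and 1058 and 439 between weeks in vector and miR-186 clones. Without a filter on low values 7 and 3 genes passed between constructs and 4 between weeks in miR-186 clones, and without miR-186 0 nM week 12 replicate 1 there was 1 between constructs at week 12 and 1 between weeks in miR-186 clones.

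A group of genes passed in the same direction between miR-186 and vector clones at both doses and weeks. ZFP42, a zinc finger protein of pluripotent cells (ENSG00000179059, chromosome 4, 187995771 to 188005050), was lower in miR-186 clones in all 4 comparisons, by 7.52-fold to 13.6-fold. At week 12 its level was 3.61 to 7.07 FPKM in single vector libraries and 0.0133 to 0.116 FPKM in miR-186 libraries. NEFL, a neurofilament chain (ENSG00000277586, chromosome 8, 24950955 to 24957110), was lower by 10.2-fold to 13.6-fold, and PRR5L, a regulator of mTORC2, by 9.44-fold to 15.4-fold. PHETA2, the homeodomain protein HOPX, the choline transporter SLC44A4, the necroptosis kinase RIPK3, the decoy receptor TNFRSF10D and the matrix protein FRAS1 were lower in all 4 too, as was WNT4 (2.10-fold to 3.01-fold).

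Genes higher in miR-186 clones in all 4 comparisons included the adhesion molecule CADM1 (4.35-fold to 6.25-fold), HDX (4.35-fold to 5.58-fold), GSPT2, a translation release factor (4.12-fold to 5.13-fold), ZNF254 (4.25-fold to 5.27-fold) and BNIP3, a mitophagy receptor (2.84-fold to 4.84-fold). The ion channel P2RX5 was higher too and was listed at 0 in vector clones at 0 nM and week 12. MED1, CDK12, CASC3, SMARCE1 and ORMDL3, which lie close together on chromosome 17, were higher by 1.84-fold to 2.51-fold over these genes and comparisons. These 5 and RIPK3 were chosen after their values were seen. In all, 32 genes were higher and 21 lower in all 4 comparisons, of 429 higher and 450 lower in at least 1, and no gene passed in opposite directions in any pair of comparisons. Per the labels the same clonal lines were kept throughout, so the 4 comparisons are not independent.

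**Figure D2:**
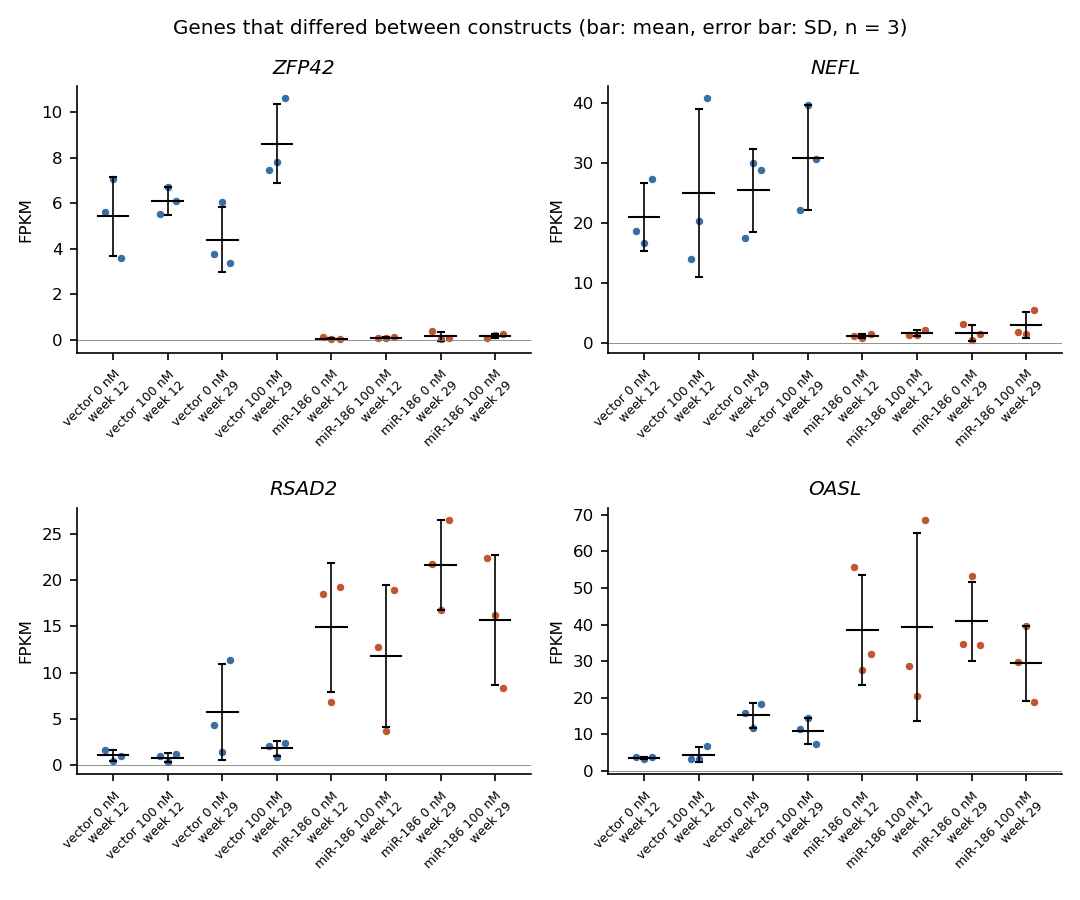
FPKM of ZFP42, NEFL, RSAD2 and OASL in the 24 libraries (points), vector in blue and miR-186 in orange; bars give the mean and error bars the SD (n = 3). ZFP42 and NEFL were lower in every miR-186 group by the test. RSAD2 did not pass at 0 nM and week 29, nor OASL at week 29.

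At 0 nM and week 12, the interferon-induced genes RSAD2 and OASL were higher in miR-186 clones by 3.26 ± 0.61 and 3.19 ± 0.39 (9.60-fold and 9.10-fold; RSAD2 14.9 ± 6.94 against 1.03 ± 0.559 FPKM, n = 3). Of 35 interferon genes 5 rose and none fell (5 and 0 adjusted over the list alone), IFI44 (1.96 ± 0.47) and HERC5 (1.70 ± 0.44) among them; the list had adjusted p = 9.27e-04, and adjusted p = 0.890 with an estimated correlation. The imprinted RNA H19 was lower by 3.10 ± 0.86 and the interleukin 33 receptor IL1RL1 by 2.88 ± 0.65. Of 27 inflammatory genes CCL5 was higher (1.89 ± 0.37) and CXCL1 (−1.66 ± 0.34) and TNFAIP2 (−1.11 ± 0.29) lower (1 and 5 adjusted over the list alone). Its adjusted p = 0.0335 became adjusted p = 0.890 with an estimated correlation. Of 29 genes of EGFR ligands and MAPK output, the receptor ERBB2 was higher (1.42 ± 0.23) and the ligand EPGN lower (−1.76 ± 0.46; 1 and 1 adjusted over the list alone). The desmosomal cadherin DSG3 was lower (−0.94 ± 0.18). limma gave 203 higher and 287 lower, and 379 and 307 with the GC correction, 269 and 223 with centring by genome window as well, and 60 and 47 in a fit on only these groups. Leaving out vector replicates 1, 2 or 3 gave 204, 230 or 234 genes, and leaving out miR-186 replicates 1 or 2 gave 252 or 185.

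At 0 nM and week 29, C4orf19 (3.67 ± 0.46; 14.7 ± 1.41 against 0.715 ± 0.279 FPKM, n = 3), AMOT, which binds YAP (2.92 ± 0.50), GABRP (2.97 ± 0.80), VGLL1 (2.71 ± 0.63) and the neurotrophin receptor NTRK2 (2.40 ± 0.56) were higher in miR-186 clones. The antimicrobial peptide DEFB1 was lower by 3.91 ± 0.95, and KRT5, the keratin of basal cells, by 1.33 ± 0.26. Of 19 genes of differentiation and cornification SPRR1B (−2.97 ± 0.73) and TGM1 (−1.43 ± 0.35) were lower and none higher (0 and 2 adjusted over the list alone; list adjusted p = 0.00137, adjusted p = 0.864 with an estimated correlation). Of 13 stress keratins and alarmins 3 were lower and none higher (0 and 7 adjusted over the list alone; median −2.28, adjusted p = 2.30e-05, adjusted p = 0.864 with an estimated correlation). These 3 are KRT6A (−2.47 ± 0.61) and the protease inhibitors SERPINB3 (−3.16 ± 0.84) and SERPINB4 (−3.05 ± 0.80), each of which has a near-identical copy that can share its reads. limma gave 251 higher and 156 lower, and 189 and 179 with the GC correction and centring by window. With the GC correction and the replicate block, whose number cannot mark a clone shared between constructs, limma gave 31 and 21. It gave 141 and 75 without a filter on low values, and 76 and 77 in a fit on only these groups. Leaving out vector replicates 1, 2 or 3 gave 95, 167 or 219 genes, and leaving out miR-186 replicates 1, 2 or 3 gave 266, 168 or 116.

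At 100 nM and week 12, RSAD2 (3.04 ± 0.61), OASL (2.89 ± 0.39), IFI44 (2.16 ± 0.47) and CMPK2 (1.88 ± 0.45) were among 5 interferon genes of 35 that were higher in miR-186 clones, with none lower (7 and 0 adjusted over the list alone). The list had adjusted p = 3.47e-05, and adjusted p = 0.890 with an estimated correlation. CENPV was higher by 2.15 ± 0.40. H19 was lower by 4.39 ± 0.86 (3.70 ± 3.57 against 88.5 ± 86.1 FPKM, n = 3), creatine kinase CKB by 2.67 ± 0.68, the serine protease PRSS21 by 2.76 ± 0.37 and ALDH3A1, an aldehyde dehydrogenase induced through AHR, by 2.04 ± 0.39. Of 15 WNT targets DKK1 (1.00 ± 0.23) was higher and WNT4 (−1.59 ± 0.25) lower (1 and 1 adjusted over the list alone). limma gave 131 higher and 156 lower, 278 and 266 with the GC correction, 98 and 87 without a filter on low values, and 12 and 12 in a fit on only these groups. Leaving out vector replicates 1, 2 or 3 gave 189, 102 or 115 genes, and leaving out miR-186 replicates 1 or 2 gave 106 or 128.

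At 100 nM and week 29, BNIP3 (2.27 ± 0.39; 5.35 ± 1.36 against 0.694 ± 0.170 FPKM, n = 3), RSAD2 (2.79 ± 0.61), C4orf19 (2.26 ± 0.46) and ZBTB10 (2.12 ± 0.49) were higher in miR-186 clones. KRT5 (−1.50 ± 0.26), H19 (−3.76 ± 0.86), the phospholipase PLCE1 (−2.35 ± 0.49), the WNT inhibitor APCDD1 (−2.21 ± 0.38), PRSS12 (−2.16 ± 0.39) and the proton pump subunit ATP6V1B1 (−2.11 ± 0.33) were lower. Of 51 mitosis genes none passed over all genes (0 and 19 adjusted over the list alone), with a median of −0.86 (adjusted p = 1.37e-09; adjusted p = 0.890 with an estimated correlation) and PLK1 at −1.29 ± 0.43. RSAD2 was the 1 interferon gene of 35 that passed (6 and 0 adjusted over the list alone; adjusted p = 8.43e-05, adjusted p = 0.890 with an estimated correlation). limma gave 65 higher and 58 lower, 113 and 73 with the GC correction, and 5 and 8 in a fit on only these groups. Leaving out vector replicates 1, 2 or 3 gave 54, 41 or 250 genes, and leaving out miR-186 replicates 1, 2 or 3 gave 48, 63 or 274.

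A few chromosomes held a larger share of the genes that passed between constructs than of the genes tested. Most genes that passed lay on other chromosomes. At 0 nM and week 12, chromosome 14 held 16.3% of them against 3.51% of the genes tested, and 76 of its 80 were lower in miR-186 clones, the TNF-induced TNFAIP2 among them. Chromosome 17 held 74, of which 70 were higher, ERBB2 and the ribosomal protein gene RPL19 (1.38 ± 0.29) among them. At 100 nM and week 12 chromosome 14 held 37, all lower, and chromosome 17 held 53, of which 48 were higher. At week 29 chromosome 17 held 56 at 0 nM, of which 54 were higher, and 28 at 100 nM, of which 24 were higher. Fisher's exact tests (1-sided) were adjusted over all chromosomes and those comparisons of 2 groups in which any gene passed. They count genes as independent draws, so their p-values do not measure agreement over clones. Fisher's exact tests gave p = 1.23e-29 and p = 2.84e-10 for chromosome 14 at 0 and 100 nM and week 12. At week 29 chromosome 14 held 28 at 0 nM, of which 27 were lower (Fisher's exact test, p = 0.0113), and 4 at 100 nM (Fisher's exact test, p = 1). For chromosome 17 Fisher's exact test gave p = 3.04e-11 at both doses at week 12, and p = 3.59e-07 and p = 4.22e-08 at 0 and 100 nM and week 29. At 0 nM, chromosome 16 held 38 at week 12, of which 36 were lower, and chromosome 9 held 31 at week 29, of which 28 were higher (Fisher's exact test, p = 0.0221 and p = 0.00883). Neither passed in its other 3 comparisons of constructs: for chromosome 16 Fisher's exact test had p = 1 at 0 nM and week 29, and p = 0.977 and p = 1 at 100 nM and weeks 12 and 29. For chromosome 9 Fisher's exact test had p = 0.526 at 0 nM and week 12, and p = 1 and p = 0.147 at 100 nM and weeks 12 and 29. Yet the median over all tested genes of chromosome 9 lay above 0 in each comparison of constructs. It was 0.16 at 0 nM and 0.14 at 100 nM at week 12, and 0.18 at 0 nM and 0.16 at 100 nM at week 29. The median over all tested genes of chromosome 14 was −0.40 at 0 nM and −0.37 at 100 nM at week 12, and −0.31 at 0 nM and −0.26 at 100 nM at week 29. Single miR-186 libraries did not all share this shift, as given for the genome windows below.

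**Figure D3:**
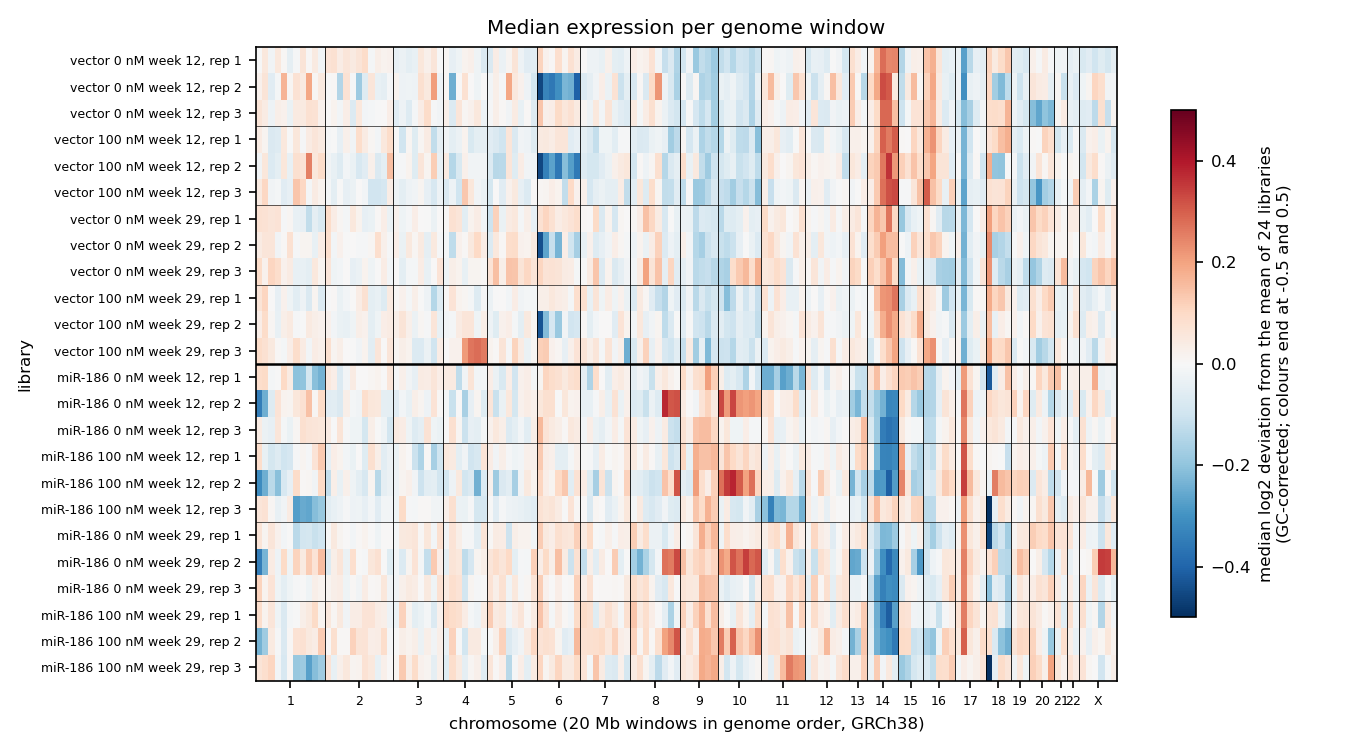
Colour gives the median log2 deviation of the genes in each 20 Mb window from their mean over the 24 libraries, after the GC correction, with libraries down the side and windows in genome order. The 160 genes at 20 to 40 Mb of chromosome 17 lay at −0.30 to −0.18 in vector libraries and 0.03 to 0.35 in miR-186 libraries.

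Genes named as targets of miR-186 in earlier literature did not pass in any comparison between constructs. BUB1, a kinase of the spindle checkpoint, stood at −0.14 and −0.31 at 0 nM and weeks 12 and 29, and at −0.64 and −0.88 at 100 nM (± 0.41, n = 3). CDC27, a subunit of the anaphase-promoting complex, stood at −0.28 and 0.16 at 0 nM and at −0.25 and 0.24 at 100 nM (± 0.24). Of 10 measured genes of this list 0 rose and 0 fell at 0 nM (0 and 1 at week 12, the transcription factor YY1 at −0.58 ± 0.17, and 1 and 0 at week 29, the scaffold AKAP12 at 1.68 ± 0.50, adjusted over the list alone). The 939 genes with the 8mer ATTCTTTA, the site that pairs with the miR-186-5p seed, in their 3' UTR differed from 4678 genes without the 6mer by −0.15 and 0.28 at 0 nM and weeks 12 and 29, and by 0.091 and 0.17 at 100 nM. These ranked 33, 137, 140 and 137 from the lowest of 168 motifs with the same bases, and with the GC correction the differences were 0.042, 0.015, 0.023 and −0.037. The 3213 genes with the 7mer ATTCTTT differed by −0.14 and 0.26 at 0 nM and weeks 12 and 29, and by 0.088 and 0.16 at 100 nM. Without the GC correction, their ranks were 13, 34, 35 and 29 from the lowest of 42 motifs.

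From week 12 to week 29 at 0 nM in vector clones, PTGS2, the inducible cyclooxygenase (ENSG00000073756, chromosome 1, 186671791 to 186680427), fell by 3.53 ± 0.66 (139 ± 72.6 to 11.3 ± 5.07 FPKM, n = 3), NR4A1, an orphan nuclear receptor, by 3.28 ± 0.75, EGR2 by 3.15 ± 0.64 and FOSB, a subunit of AP-1, by 2.98 ± 0.52. The cytokine IL6 fell by 2.77 ± 0.48, the matricellular protein CCN2 by 2.67 ± 0.33 and the stress factor ATF3 by 2.56 ± 0.31 (591 ± 233 to 95.5 ± 14.9 FPKM). OASL (1.92 ± 0.39), the calcium buffer CALB1 (1.45 ± 0.30), the small nucleolar RNA host SNHG3 (0.94 ± 0.22), the stress factor DDIT3 (0.86 ± 0.20) and the kinase SYK (0.63 ± 0.14) rose. limma gave 12 rises and 117 falls, 30 and 199 with the replicate block (each pair of libraries with 1 number had correlated deviations), 34 and 192 with it as a random block, 33 and 117 with the GC correction, 102 and 256 with both, and 8 and 59 in a fit on only these groups. Leaving out week 12 replicates 1 or 2 gave 71 or 43 genes, and leaving out week 29 replicates 1 or 3 gave 48 or 57.

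In miR-186 clones the same weeks gave falls of NR4A1 (−4.04 ± 0.75; 60.5 ± 31.4 to 5.10 ± 6.89 FPKM, n = 3), FOSB (−3.52 ± 0.52), CSRNP1, an AXIN1-induced nuclear protein (−3.36 ± 0.24), PTGS2 (−3.09 ± 0.66), SMAD7, an inhibitor of TGF-beta signalling (−2.84 ± 0.39) and the secreted phospholipase PLA2G2A (−2.72 ± 0.70). Week 29 replicate 2 stood above replicates 1 and 3 in PTGS2 (76.4 against 8.23 and 9.80 FPKM), FOSB (51.0 against 6.33 and 12.2 FPKM) and NR4A1 (13.0 against 0.869 and 1.37 FPKM). PTGS2 no longer passed without week 12 replicate 1 or 2 or week 29 replicate 1 or 3, and NR4A1 without week 12 replicate 1. TMEM156 (2.46 ± 0.57), KLHL5 (1.86 ± 0.42), the small nucleolar RNA host SNHG1 (2.15 ± 0.36; 136 ± 91.6 to 528 ± 91.8 FPKM), MOCOS (1.32 ± 0.33) and the stress gene DDIT4 (1.27 ± 0.26) rose. limma gave 223 rises and 189 falls, 125 and 190 with median ratio scaling, and 125 and 190 with the GC correction, which kept 221 genes. It gave 11 and 90 in a fit on only these groups. Leaving out week 12 replicates 1, 2 or 3 gave 60, 103 or 916 genes, and leaving out week 29 replicates 1 or 3 gave 119 or 106. No gene passed the test for a difference in the miR-186 effect between weeks: limma gave 0, 1910 at unadjusted p under 0.05, 4 without a filter on low values and 1 without miR-186 0 nM week 12 replicate 1, with the motor protein MYO1E at 1.14 ± 0.23 and FILIP1L at 2.04 ± 0.42 (adjusted p = 0.257 for both).

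**Figure D4:**
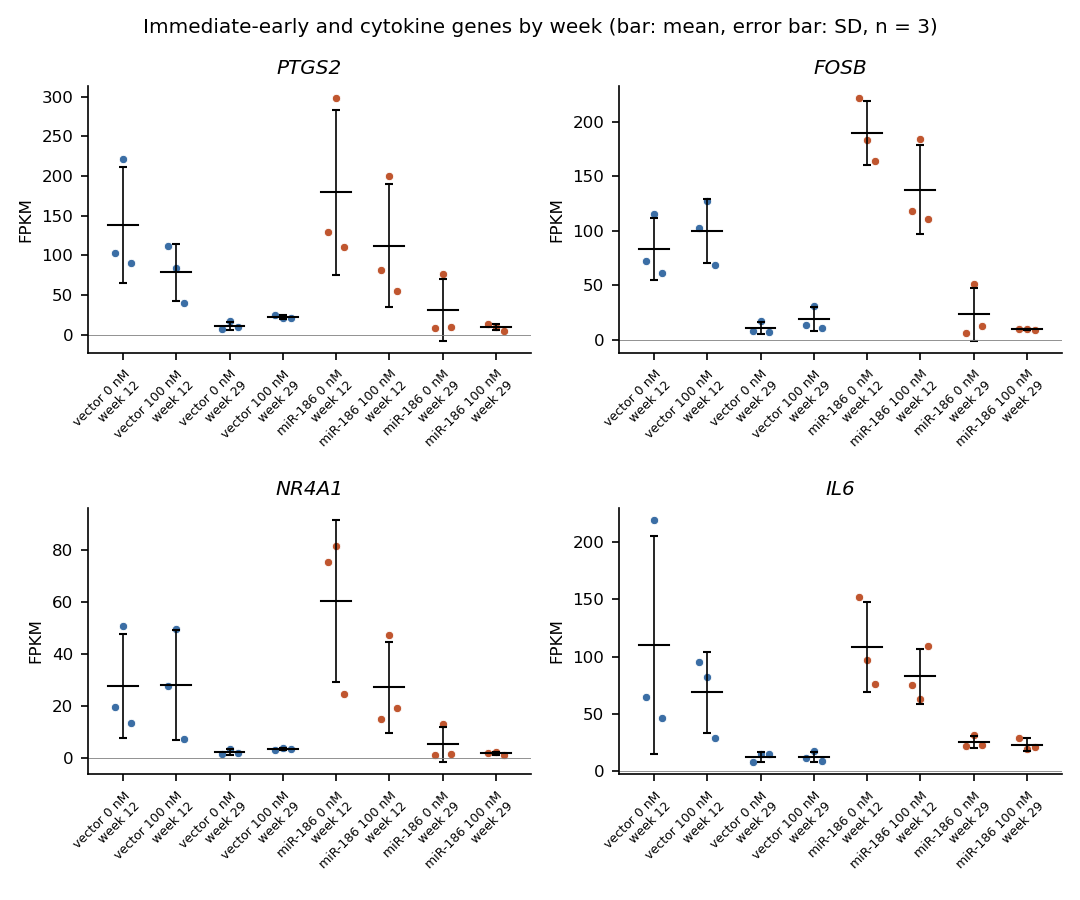
FPKM of PTGS2, FOSB, NR4A1 and IL6 in the 24 libraries (points), by group; bars give the mean and error bars the SD (n = 3). In vector libraries of both doses PTGS2 ran from 40.2 to 222 FPKM at week 12 and from 7.12 to 25.6 FPKM at week 29.

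Of 29 genes of EGFR ligands and MAPK output, 7 fell in vector clones and 11 in miR-186 clones over these weeks, and none rose (0 and 14, and 0 and 15, adjusted over the list alone). IER3, an early response gene, fell by 1.54 and 1.97 (± 0.17) in vector and miR-186 clones and the ligand HBEGF by 1.98 and 1.49 (± 0.27), JUN by 1.43 ± 0.21 in vector clones, and the phosphatase DUSP4 fell by 1.89 ± 0.27 in miR-186 clones. The list medians were −0.59 in vector clones (adjusted p = 1.52e-12; adjusted p = 0.0142 with an estimated correlation) and −0.92 in miR-186 clones (adjusted p = 1.19e-07; adjusted p = 0.0885 with an estimated correlation). Of 27 inflammatory genes 5 and 6 fell (1 and 10, and 0 and 8, adjusted over the list alone), NFKBIZ by 1.77 and 2.01 (± 0.25) among them, with adjusted p = 8.24e-04 and adjusted p = 0.00259, and for both adjusted p = 0.890 with an estimated correlation.

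Other lists held members that passed over the same weeks. Of 18 YAP and TEAD targets CCN2, CCN1 (−1.79 ± 0.35) and the kinase LATS2 (−0.77 ± 0.16) fell in vector clones (0 and 5 adjusted over the list alone; adjusted p = 4.34e-04, adjusted p = 0.814 with an estimated correlation). Of 25 p53 targets 4 fell in vector clones, the growth arrest gene GADD45A (−1.45 ± 0.18) among them (1 and 5 adjusted over the list alone), and in miR-186 clones the CDK inhibitor CDKN1A fell (−1.66 ± 0.24) and the DNA repair gene XPC rose (1.06 ± 0.27; 1 and 6 adjusted over the list alone). Of 28 genes of the unfolded protein and integrated stress response PPP1R15A (−1.50 and −1.39, ± 0.17) and ATF3 fell and DDIT3 rose in both constructs (2 and 2, and 3 and 2, adjusted over the list alone). The AHR target TIPARP fell by 1.63 and 1.58 (± 0.26). Over all 31 lists and 15 comparisons, camera gave 103 of 465 tests past the threshold, 1 with an estimated correlation, and 78 of 100 groupings of the libraries, the real one included, gave as many. These groupings mix weeks, doses and constructs, so the share cannot decide on chance.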

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

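The tests of explanations in this part, and the corrections for GC content and genome windows, were chosen only after the results were seen. The tests of differences between lists were planned.

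Differences between effects that passed the list test were 27, of which 22 passed with the GC correction and 0 with an estimated correlation (camera in limma, smallest adjusted p = 0.595 with an estimated correlation). Each stood out as a difference between groups in the same effect, as a median log2 difference. The iAs effect at week 12, miR-186 minus vector, was −0.52 for antigen presentation, −0.47 for mitosis, −0.37 for DNA replication, 0.25 for the integrated stress response and 0.41 for mitochondrial messages. At week 29 it was −0.59 for mitosis, −0.40 for EGFR ligands and MAPK output, −0.23 for YAP and TEAD targets and 0.44 for ribosomal proteins. Between weeks in miR-186 clones, week 29 minus week 12, it was −0.88 for mitochondrial messages, −0.37 for the integrated stress response, 0.19 for hypoxia and glycolysis, 0.24 for mitosis, 0.27 for ribosomal proteins and 0.31 for DNA replication. Between weeks in vector clones it was −0.51 for interferon genes, −0.23 for antigen presentation, 0.32 for heat shock and 0.43 for mitosis. The miR-186 effect between weeks at 0 nM differed by −1.25 for metallothioneins, −0.47 for DNA replication, −0.34 for ribosomal proteins, −0.32 for differentiation and cornification, −0.31 for mitosis, −0.27 for hypoxia and glycolysis, −0.26 for antigen presentation and 0.42 for mitochondrial messages. Some differences in the iAs effect turned sign when 1 replicate number was left out. These were the integrated stress response between constructs at week 12, and mitosis and ribosomal proteins between weeks in miR-186 clones.

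The genes called for iAs in vector clones at week 12 may follow a GC content trend between libraries. Of the 197 genes, 5 passed after the GC correction, as their median change went from 0.84 to 0.47 while the median SE went from 0.183 to 0.149. The calls ended because the changes shrank, not because the spread grew. An iAs response apart from the GC trend stays open: with the correction, 67.5% of the 197 had the same sign at week 29, and in miR-186 clones 84.8% at week 12 and 52.3% at week 29. The trend goes with dose at week 12, so beyond the 5 genes trend and response cannot be told apart. NEAT1 was 1 of the 5 genes (1.40 ± 0.25, and 1.63 ± 0.24 with the correction). The prediction for NEAT1 was written after its corrected value was seen, so it is no test of the trend as the cause.

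The calls of miR-186 against vector may come in part from chromosome segments that differ between clones. Among 12393 genes not called in these comparisons, 3 of 138 windows had every miR-186 library on 1 side of every vector library, against at most 1 in 100 shuffles of gene positions; the 24 libraries come from 6 clones. Shifts of whole windows as the only source of the calls are argued against. Of the 1307 calls over the 4 comparisons, 57.2% (747) passed after the GC correction and centring in windows. Centring takes out only the median of a window, so it cannot decide on segments shorter than a window or crossing its edge. MED1, CDK12, CASC3, SMARCE1 and ORMDL3, higher in all 4 comparisons, lie close together on chromosome 17. Segments of any length as the whole of the calls therefore stay open. Of 415 lower genes with a 3' UTR, 24 (5.78%, 95% interval 3.74% to 8.48%) had an 8mer site of miR-186-5p, against 7.89% of all tested genes with a 3' UTR. Direct repression through 8mer sites is therefore argued against for most lower genes, as most lack one. Most tested genes lack one too, so this outcome was near certain in advance and does not measure the effect of miR-186. For genes that have a site it stays open, with ranks of 132, 51, 120 and 25 from the lowest of 168 motifs with the GC correction, as do, untested, other routes of miR-186 and differences between clones unrelated to it.

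The fall of EGFR ligand and MAPK output genes from week 12 to week 29 does not rest on the GC content trend alone. Of the 18 falls of list members over both constructs, 15 passed with the GC correction. At 100 nM the list's median change over the same weeks was −0.57 in vector clones and −0.72 in miR-186 clones. The state of the cultures at harvest, such as density or time since feeding, was not measured here. If it differed with week, it could not be told apart from an effect of time in culture.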

How the results depend on the processing

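The GC correction, alone, with centring in windows or with the replicate block, was chosen only after the results were seen; the other alternatives were planned. Counts are genes past limma's threshold, and for each change the cause was not tested unless stated. Read counts were not used here, so what depth limits was not measured beyond the relative depth. With 3 libraries per group, the spread is shared over all groups, and a fit on only the groups compared has fewer libraries.

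Without a filter on low values, more genes are tested together, and iAs gave 0 genes in vector clones at week 12 (5294 at unadjusted p under 0.05), 19 in miR-186 clones at week 12 and 3 at week 29. There miR-186 against vector gave 216 at 0 nM and week 29 and 185 at 100 nM and week 12. The iAs effect differed between constructs for 7 genes at week 12 and 3 at week 29, and between weeks in miR-186 clones for 4, and the miR-186 effect between weeks for 4. A mean of at least 2 FPKM gave 504 for iAs in vector clones at week 12, and median ratio scaling 494. In the fits on only the groups compared that comparison gave 0 (4132 at unadjusted p under 0.05). There the constructs gave 107 and 153 at 0 nM and weeks 12 and 29, and 24 and 13 at 100 nM, and the weeks gave 67 in vector and 101 in miR-186 clones.

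With the GC correction iAs gave 7 in vector and 1 in miR-186 clones at week 12, with or without centring in windows, and the constructs gave 544 and 186 at 100 nM and weeks 12 and 29. Sites of miR-186 with the GC correction differed by 0.042 and 0.015 at 0 nM and weeks 12 and 29, and by 0.023 and −0.037 at 100 nM, with the sign turned at 0 nM and week 12 and at 100 nM and week 29.

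With the replicate block iAs in vector clones at week 12 gave 1428, the weeks 229 in vector and 1381 in miR-186 clones, and the constructs 56 at 0 nM and week 12, 48 at 100 nM and week 12, and 0 at 100 nM and week 29 (1264 at unadjusted p under 0.05). With the GC correction and the replicate block iAs gave 3 in vector and 1 in miR-186 clones at week 12, the weeks 358 and 957, and the constructs 9 and 52 at 0 nM and weeks 12 and 29, and 73 and 1 at 100 nM. Where numbers pair the libraries, the replicate block changed no other count by over 1.5 times. In vector clones at week 12 the libraries of both doses correlated best with their own number, at 0.071, 0.71 and 0.44, as they did between constructs at 100 nM and week 12, a hint from the data and not from the design. In the other unpaired comparisons of 2 groups not every library did. Genes are not independent replicates in these correlations. Construct and replicate number as a random block (correlation 0.151), a stand-in for the clone that the labels do not give and that may mix clones across doses in miR-186 libraries, gave 1680 for iAs in vector clones at week 12, and 226 and 1147 between weeks in vector and miR-186 clones.

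Leaving out 1 library gave 0 to 1 genes for iAs in vector clones at week 12, and 0 to 1 in miR-186 clones at week 12 (1 without miR-186 0 nM week 12 replicate 1 or 3). It gave 0 to 1 for the difference between constructs at week 12, between weeks in miR-186 clones and in the miR-186 effect between weeks (1 without miR-186 0 nM week 12 replicate 1). The constructs gave 185 (without miR-186 replicate 2) to 454 (without miR-186 replicate 3) and 95 (without vector replicate 1) to 266 (without miR-186 replicate 1) at 0 nM and weeks 12 and 29. At 100 nM they gave 102 (without vector replicate 2) to 289 (without miR-186 replicate 3) and 41 (without vector replicate 2) to 274 (without miR-186 replicate 3). The weeks gave 43 (without week 12 replicate 2) to 110 (without week 12 replicate 3) in vector and 60 (without week 12 replicate 1) to 916 (without week 12 replicate 3) in miR-186 clones.

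Of 465 list tests 1 passed with an estimated correlation. The GC correction gave 121, of which 91 were among the 103, and the other settings gave 83 of 341 tests (replicate block), 98 of 450 (at least 2 FPKM) and 104 of 525 (no filter) to 126 of 465 (without replicate 3). Medians that turned sign were those of DNA replication, iAs in miR-186 clones, week 12 (0.15 without replicate 1, −0.66 without replicate 3) and mitochondrial messages at week 29 (0.097 without replicate 2, −0.52 without replicate 1). Interferon genes between constructs at 0 nM and week 29 turned too (−0.23 without replicate 2, 0.68 without replicate 3). Of differences in the iAs effect, the integrated stress response between constructs at week 12 (−0.12 without replicate 1, 0.58 without replicate 3), and mitosis (−0.18 without replicate 1, 0.90 without replicate 2) and ribosomal proteins (−0.044 without replicate 2, 0.52 without replicate 1) between weeks in miR-186 clones turned as well.

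Of genes taken by the rule, 603 results lay on the same side of the threshold with either pseudocount and with median ratio scaling, 571 with the GC correction (33 no longer passed, 11 newly passed) and 543 with the replicate block (38 and 34). They were 519 in the fits on only the groups compared (90 and 6), 521 with the GC correction and the replicate block (78 and 16), and 545 without a filter on low values (70 no longer passed). ANAPC2 turned from −0.76 to 0.0064 in the miR-186 effect between weeks with the GC correction and centring in windows, and ALDOC from 0.41 to −0.025 for iAs in miR-186 clones at week 29 without miR-186 100 nM week 29 replicate 2 (0.73 without replicate 1 of that group). Leaving out 1 library left 4156 values on the same side, 443 no longer passed, 36 newly passed and 1 turned.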

Other observations

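The tests of replicate numbers against window profiles and of other splits of the libraries were chosen only after the results were seen. The list tests were planned.

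Several gene groups held few changes. Of 9 replication-dependent histone genes, H2BC4 fell from week 12 to week 29 in miR-186 clones (−1.46 ± 0.31) and none rose (0 and 3 adjusted over the list alone; median −0.61, adjusted p = 0.0358, adjusted p = 0.890 with an estimated correlation). In vector clones 0 of the 9 passed in limma (0 and 4 adjusted over the list alone; median −0.55, adjusted p = 0.00352, adjusted p = 0.890 with an estimated correlation). Of 15 mesenchymal genes, TAGLN, an actin-binding protein of smooth muscle, fell in vector clones over the same weeks (−2.06 ± 0.45; 0 and 4 adjusted over the list alone; adjusted p = 0.00715, adjusted p = 0.814 with an estimated correlation). The small heat shock protein HSPB8 fell there as well (−1.77 ± 0.34). Of 30 hypoxia and glycolysis genes, ANKRD37 (−0.99 ± 0.24) and ALDOC (−1.31 ± 0.32) fell in miR-186 clones (0 and 7 adjusted over the list alone; adjusted p = 4.34e-04, adjusted p = 0.864 with an estimated correlation). AGO2, which holds the guide strand of microRNAs, was higher in miR-186 clones at 0 nM and week 12 (0.93 ± 0.25), as 1 of 13 genes of the microRNA machinery (2 and 1 adjusted over the list alone; list adjusted p = 0.207).

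Markers of other cell types were measured as well. CDH5, a cadherin of endothelium, averaged 12.0 FPKM over the 24 libraries (3.67 to 20.7), MITF 5.62 FPKM (1.94 to 9.57) and PMEL 1.23 FPKM (0.708 to 2.31) of melanocytes, and CD68 of macrophages 3.32 FPKM (0.853 to 7.25). MAGED1, a widely expressed gene placed on the list of cancer-testis antigens, averaged 15.7 FPKM (5.03 to 32.1). No other member of the lists of these genes was among the genes tested, so they are no sign of those cell types. None of the 5 measured fibroblast genes passed in limma in the 10 comparisons of 2 groups, 0 adjusted over the list alone as well, with list medians of −0.91 (adjusted p = 0.236) and −0.65 (adjusted p = 0.154) between weeks in vector and miR-186 clones.

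Some genome windows stood apart in single libraries, as median log2 deviations. On chromosome 6, 0 to 20 Mb (83 genes), vector replicate 2 lay at −0.45, −0.45, −0.44 and −0.43 in its 4 groups. On chromosome 1, 0 to 20 Mb (196 genes), miR-186 replicate 2 lay at −0.35, −0.31, −0.35 and −0.24. On chromosome 14, 80 to 100 Mb (70 genes), vector libraries lay at 0.14 to 0.36. There miR-186 libraries lay at −0.41 to −0.22, except 0 nM week 12 replicate 1 (0.08), 100 nM week 12 replicate 3 (0.07) and 100 nM week 29 replicate 3 (0.05). On chromosome 9, 80 to 100 Mb (89 genes), all vector libraries (−0.18 to −0.04) lay below all miR-186 libraries (0.07 to 0.19). On chromosome 18, 0 to 20 Mb (49 genes), miR-186 libraries at −0.42 (0 nM week 12 replicate 1), −0.50 (100 nM week 12 replicate 3), −0.46 (0 nM week 29 replicate 1), −0.21 (0 nM week 29 replicate 3) and −0.64 (100 nM week 29 replicate 3) lay below vector libraries (0.07 to 0.24).

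From these profiles, a hypothesis is that the replicate number marks 1 clone across groups, so matches of the same profiles are no independent test of it. Among vector libraries, 33 of 36 best matches of window profiles between groups joined the same number (permutation p = 0.0037 over 10000 renumberings, median 12, highest 33). Among miR-186 libraries 20 of 36 did (permutation p = 0.10). With numbers 1 and 3 exchanged in the 100 nM groups, 36 of 36 did. This exchange was read off the same best matches and is the highest of the renumberings, so it is no test (chromosome 18 is low in both replicates 1 and 3 at 0 nM and week 29), and whether replicate numbers 1 and 3 are exchanged between the doses stays open. The labels do not tie numbers to clones, and libraries were used as labelled.

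Splits of the same libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05. For iAs, the real split and the highest other gave 197 and 2 genes (1 of 10 splits as large) in vector clones at week 12, and 0 and 0 (10 of 10, as any count reaches 0) in vector clones at week 29 and in miR-186 clones at weeks 12 and 29. In limma these 3 had 555, 1558 and 312 genes at unadjusted p under 0.05. For miR-186 against vector they gave 490 and 41 at 0 nM and week 12, 407 and 1 at 0 nM and week 29, 287 and 0 at 100 nM and week 12, and 123 and 1 at 100 nM and week 29. Between weeks they gave 129 and 0 in vector clones and 412 and 56 in miR-186 clones. Where numbers pair the libraries, the other splits that part as many pairs gave no more than these highest values, and the remaining splits keep pairs on 1 side.

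For the 5 differences between effects limma gave 0 genes (421, 272, 1058, 439 and 1910 at unadjusted p under 0.05), so 100 of 100 groupings were as large by construction, which says nothing about chance. The highest other groupings gave 306 and 597 genes for the iAs effect between constructs at weeks 12 and 29, 1748 and 1487 between weeks in vector and miR-186 clones, and 58 for the miR-186 effect between weeks. Counts so far above 0 point to a structure of the samples: a grouping that mixes weeks, doses or constructs carries their main effects into the difference. An earlier draw of 100 groupings gave highest counts that differed by over 1.5 times for 2 of the 5, so these counts rest on the draw. For the 103 list calls 78 of 100 groupings gave as many, with 179 the highest. These groupings mix weeks, doses and constructs too, so the share cannot decide on chance, which is not excluded there.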
